A study of Mus musculus with 6 samples.

How the data were processed

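Total RNA from mouse ES cells was depleted of ribosomal RNA and sequenced, per the labels' protocols, in 3 libraries of a line with floxed, undeleted Zscan10 and 3 libraries of a subcloned Zscan10-null line. The submitters' processing notes name Trim Galore, FastQC, TopHat and Cuffdiff and the mouse genome build mm10; their versions and roles are not given in the sources used here. The deposited files hold 1 value per locus and library, with a gene symbol and RefSeq transcript accessions per the file headers. No label or header states the unit. The values were taken as FPKM that the authors had made, because they are not whole numbers, the smallest values above 0 belong to long genes and the largest to short RNAs, and the totals differ between libraries, which TPM would not. Whether the authors scaled the libraries to each other is not given in the sources used here, and it is not stated whether strand was used, so overlapping antisense genes could share fragments. FPKM of loci shorter than a fragment, such as microRNA and snoRNA genes, is unstable, and a 0 there can be a failed estimate. Loci of multi-copy families can share reads.

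Each file holds 23244 loci, of which 4768 were at 0 in every library. Loci were placed on GRCm38.p6, which is mm10, by RefSeq accession, symbol or synonym: 22851 were placed and 393 were not, 351 of these being extra copies of 1 accession. GC content and length came from the longest GENCODE M21 transcript. No raw count is in the files used here, so depth was read from low values. Among protein-coding genes below 0.15 FPKM, 86.5% of 2923 values were whole multiples of the smallest value within a tolerance of 1%. These steps gave a relative depth of 1 for control replicate 1, 1.09 and 0.996 for control replicates 2 and 3, and 0.986, 1.09 and 0.999 for null replicates 1 to 3. With transcript lengths, 258 genes gave a median of about 7950000 fragments for control replicate 1, a rough estimate. At this depth a gene of low FPKM rests on few fragments.

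The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on log2(FPKM + 1), over loci with a mean of at least 1 FPKM across the 6 libraries, with the values scaled as deposited, no covariate, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Ratios of group means are given without a pseudocount. Errors are SDs over 3 libraries unless an SE is named. Camera was run with a preset inter-gene correlation of 0.01, and again with an estimated correlation, on 20 gene lists and on the genes of each chromosome. The lists were fixed before the data were examined: naive pluripotency, formative and primed epiblast, endoderm, mesoderm, neuroectoderm, trophectoderm, 2-cell-like, germline, imprinted, p53 targets, DNA repair, glutathione, RNA exosome, SCAN-domain paralogs, fibroblast, cell cycle (proliferation), hypoxia and glycolysis, stress and immediate-early, signalling targets and interferon. Of their 420 symbols 416 were found. Genes within 500 kb of Zscan10 were counted separately.

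The named genes were fixed by a rule before the data were examined: Zscan10; the 12 largest rises and 12 largest falls among loci past the threshold whose groups do not overlap and whose higher mean is at least 2 FPKM, leaving out unnamed, predicted and short RNA loci; Pou5f1, Nanog, Sox2, Esrrb, Klf4 and Zfp42; up to 4 members per list past the threshold, or the 2 with the highest FPKM where fewer than 2 passed; and genes within 500 kb of Zscan10 past it. Some of the genes this rule takes are not reported here by name. Genes outside the rule were named after their values were seen. In the lists these are Lamc1, Cubn, Gata4 and Sparc (endoderm), Nodal, Axin2 and Id1 (signalling), and Col1a1, Col1a2, Col3a1, Col5a1 and Col5a2 (fibroblast). In the cell cycle list they are Mki67, Top2a, Ccnb1, Plk1, Aurka, Aurkb and Bub1. The others are the Zscan4 genes, the chromosome Y genes and the genes of the closing observations.

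The test was tried on simulated data for this comparison, in 5 runs on 11480 genes with 200 changed genes each: 28% of 1.25-fold, 70% of 1.5-fold, 81.6% of 2-fold and 97.6% of 3-fold changes were recovered, and 5.07% of the calls were unchanged genes. Only 200 genes changed in each run, against 2894 loci called in the real data. The adjustment was therefore stricter in the simulation, and the recovered shares do not carry over directly to these data. Camera called 100% of sets of 20 genes shifted by 0.3 and 0% of unshifted sets. The simulated genes varied independently of each other, while the estimated correlation was 0.43 in the endoderm list and 0.36 in the 2-cell-like list. These shares therefore do not show camera's error for lists whose genes move together. Alternatives changed the pseudocount, the filter, the scaling, the variance estimate, a replicate block, the set test, the window and each library in turn. Alternatives that need raw counts were not run, since the files hold FPKM. The smooth fits used mgcv 1.9.3, and figures were drawn with matplotlib 3.10.9.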

Results

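Gene expression was measured by RNA sequencing in mouse embryonic stem (ES) cells, the self-renewing cells derived from the early embryo, to ask how much expression differs when the zinc-finger gene Zscan10 is absent. The 6 libraries formed 2 groups of 3: ES cells with a floxed but undeleted Zscan10 (floxed control) and a subcloned Zscan10-null ES cell line (null). The sources used here do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Because the null cells were a subclone, a difference between the groups is a difference between a null subclone and its control, and clone and genotype cannot be separated. The titles of the control libraries carry the mark -Tx and those of the null libraries do not. Any difference in treatment between the groups cannot be separated from clone and genotype either. Each file listed 23244 loci, of which 16266 to 16567 had a value above 0 in a library. The FPKM values summed to 688125, 699401 and 685905 in the control libraries and to 678200, 670936 and 664555 in the null libraries. The steps between low values placed the depth of the other 5 libraries at 0.986 to 1.09 times that of control replicate 1, and put control replicate 1 at about 7950000 fragments. Correlations of log2 values were 0.975 to 0.983 within a group and 0.962 to 0.976 between groups.

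Zscan10, a SCAN-domain zinc-finger gene on chromosome 17 (mm10, 23600826 to 23611019), fell from 43.0 ± 1.14 FPKM in the control to 5.13 ± 0.607 FPKM in the null libraries (mean ± SD, n = 3 each). The remaining 11.9% of the control level was present in each null library, at 5.49, 4.43 and 5.47 FPKM. The log2 fold change was -2.85 with an SE of 0.08 and a limma adjusted p of 2.88e-06. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 20 assignments allow. The files give 1 value per locus, so it is not known which exons the remaining fragments came from.

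The core pluripotency transcription factors stayed at high levels in both groups. Pou5f1 was at 538 ± 11.9 FPKM in control and 513 ± 28.2 in null libraries (adjusted p = 0.302), Sox2 at 272 ± 3.42 and 268 ± 7.56 (adjusted p = 0.617), Nanog at 225 ± 7.37 and 248 ± 27.5 (adjusted p = 0.245), and Klf4 at 36.1 ± 1.28 and 32.2 ± 3.86 (adjusted p = 0.174). For these 4 factors the null and control libraries overlapped. Esrrb and Zfp42 fell slightly, Esrrb from 171 ± 5.15 to 147 ± 4.96 FPKM (log2 fold change -0.21, SE 0.04, adjusted p = 0.00941) and Zfp42 from 596 ± 17.1 to 508 ± 34.9 FPKM (-0.23, SE 0.05, adjusted p = 0.0188).

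**Figure D1:**
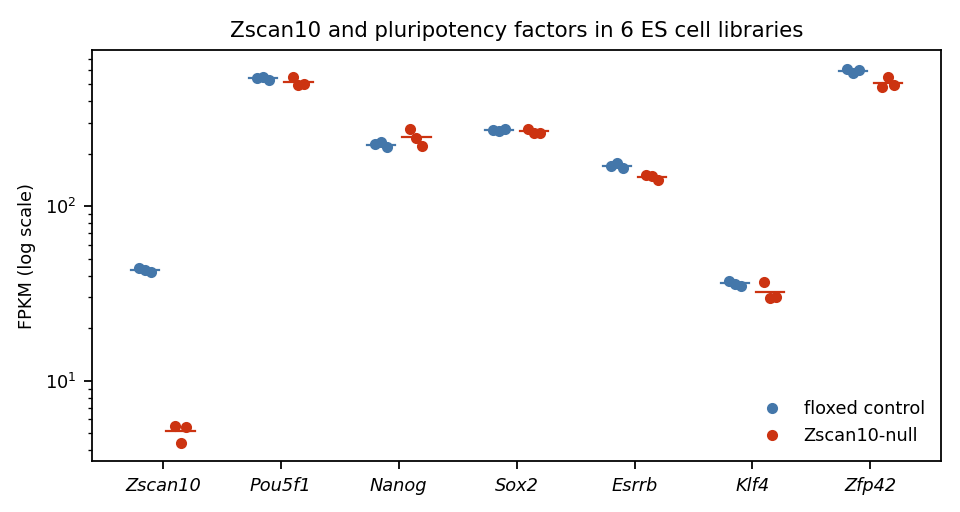
FPKM on a log axis for Zscan10 and 6 pluripotency factors in the 3 floxed control and 3 null libraries, each point a library and each line a group mean. Zscan10 lies at 43.0 FPKM in control and 5.13 in null libraries, while Pou5f1 lies at 538 and 513.

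Across the 11480 loci tested, 2894 (25.2%) passed an adjusted p of 0.05, 1468 higher and 1426 lower in null libraries. Most of these differences were small: the median absolute log2 fold change of the called loci was 0.35, and 2141 of them (74.0%) lay under 0.5. Only 99 changed at least 2-fold on the log2(FPKM + 1) scale, 63 higher and 36 lower. The values of the groups did not overlap for 44.1% of the tested loci, against 10% by chance. Leaving out control replicate 1 or 2 lowered the count of changed loci to 1741 and 1697, and a pseudocount of 0.1 raised the count of 2-fold changes to 230.

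Among the named genes with the largest rises, Sfmbt2, a Polycomb-group gene imprinted in mouse that hosts a microRNA cluster, rose from 17.2 ± 0.354 to 63.4 ± 6.98 FPKM (3.68-fold, adjusted p = 3.78e-05). Slc30a2, a zinc transporter, rose from 4.06 ± 0.0915 to 14.4 ± 0.564 FPKM. The autophagy gene Gabarapl2 rose from 130 ± 4.72 to 344 ± 31.2 FPKM, and Mylpf, a myosin regulatory light chain, from 111 ± 0.708 to 289 ± 16.7. Alox5ap, which acts in leukotriene synthesis, rose from 4.33 ± 0.295 to 12.9 ± 0.773, and Tle6, part of the subcortical maternal complex of the oocyte, from 4.29 ± 0.413 to 12.5 ± 1.30. Cbx8, a subunit of Polycomb repressive complex 1, Zfp467, Fbxo36 and Pramel7 rose from means of 0.293, 0.236, 0.848 and 2.07 FPKM to 2.93, 2.48, 4.0 and 7.05. The adjusted p-values of these genes ran from 1.03e-05 for Mylpf to 0.00251 for Pramel7.

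Among the genes named by the rule, Esr1, the estrogen receptor alpha gene on chromosome 10 (mm10, 4611989 to 5005633), fell the most, from 11.7 ± 0.704 to 0.0567 ± 0.0291 FPKM (log2 fold change -3.58, SE 0.08, adjusted p = 1.28e-06). The values of the 6 libraries, times depth, were whole multiples of the lowest, which correspond to 386, 467 and 386 fragments in control and to 1, 2 and 3 in null libraries. The control mean was 206 times the null mean, with an interval of 94.5 to 560 that covers counting error in the 6 null fragments only. Lama1, a laminin chain, fell from 23.9 ± 0.795 to 6.92 ± 1.78 FPKM, the axon guidance gene Ntn1 from 11.2 ± 0.249 to 2.95 ± 0.612, and the neurofilament gene Nefl from 9.42 ± 0.508 to 2.64 ± 0.252. Shisa2 fell from 12.05 ± 0.618 to 3.74 ± 1.12, the glycoprotein hormone gene Stc2 from 9.88 ± 0.480 to 3.49 ± 0.60, and the imprinted adaptor gene Grb10 from 5.85 ± 0.438 to 1.43 ± 0.139. Srgn, Pga5 and Serpinf1 fell from means of 4.07, 6.89 and 4.63 FPKM to 0.920, 1.91 and 1.16. Xlr3a and Hist3h2ba, from 2.04 to 0.107 and from 42.5 to 17.4 FPKM, belong to multi-copy families whose near-identical copies can share reads, so their values are uncertain. Adjusted p-values of these lower genes, Esr1 aside, ran from 8.11e-05 for Nefl to 0.0109 for Hist3h2ba. Ntn1, Stc2, Grb10, Serpinf1 and Hist3h2ba lie on chromosome 11, as does Cbx8, which rose. As described later, the genes of that chromosome were lower as a group, with a median log2 fold change of -0.12, much smaller than these falls.

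**Figure D2:**
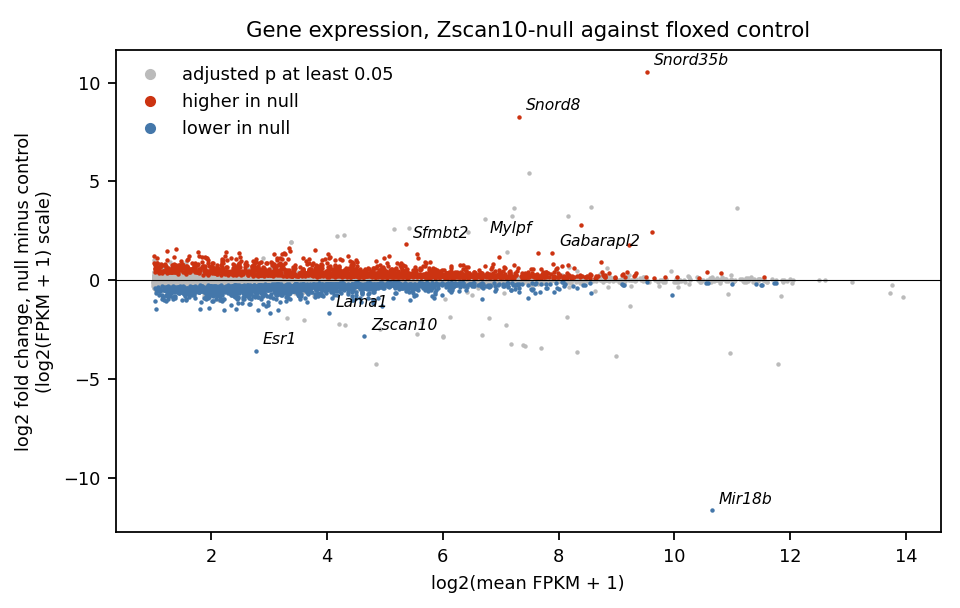
Log2 fold change (null minus control) against log2(mean FPKM + 1) for the 11480 tested loci, coloured by the limma call. Zscan10 lies at -2.85 and Esr1 at -3.58; Mir18b, Snord8 and Snord35b, which had 0 in every library of a group, lie farther from 0.

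Of 20 gene lists fixed before the data were examined, 7 differed from the other tested loci by camera with a preset correlation of 0.01. With an estimated correlation 0 did. In the cell cycle and trophectoderm lists the estimate was -0.011 and -0.0095, below the preset value. Genes that move together therefore do not account for the loss of those calls. The list calls depend on the version of the test and are weak evidence. The preset version also called up to 6 lists in other splits of these 6 libraries. Those splits keep part of the group difference, so their calls do not show how often chance alone gives one. The 2-cell-like list, genes switched on in the 2-cell embryo and in a rare ES cell state, had 16 of 19 tested members higher and 0 lower, with a median log2 fold change of 0.82 (adjusted p = 8.36e-10 with the preset correlation, 0.288 with an estimated correlation). The count adjusted over the list alone was also 16. Usp17le rose from 4.26 ± 0.327 to 14.2 ± 4.50 FPKM, Usp17la from 1.56 to 5.99, Tdpoz3 from 0.831 to 3.28 and Gm5662 from 6.49 to 15.5. Usp17l and Tdpoz genes are multi-copy families, so reads may be shared among copies and the single values are uncertain.

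The cell cycle list was modestly higher: 14 of 25 members rose and 1 fell, with a median of 0.19 (adjusted p = 2.20e-04, and 0.183 with an estimated correlation). Adjusted over the list alone, 16 rose and 3 fell. Among them Ccne2 and Ccne1, the E-type cyclins, rose from 3.86 to 5.66 and from 68.5 to 86.8 FPKM, Rrm2, a ribonucleotide reductase subunit, from 107 to 143 and the replication licensing gene Cdc6 from 19.2 to 24.8. The rise did not cover the whole list. Mki67 was at 67.3 and 68.7 FPKM (limma adjusted p = 0.607), and Top2a, Ccnb1 and Plk1 were also among the 10 members that did not pass. Of the mitotic kinase genes, Aurkb fell from 37.6 to 32.8, while Aurka and Bub1 rose from 66.6 to 76.1 and from 60.7 to 69.6.

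Genes of the trophectoderm list, markers of the placental lineage, were higher for 5 of 9 members and lower for 1, with a median of 0.23 (adjusted p = 0.0408, and 0.288 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell. Esx1 rose from 0.459 to 1.58 FPKM and Krt19 fell from 6.21 to 2.85. In the mesoderm list 2 of 5 members rose and 0 fell, or 3 adjusted over the list alone (median 0.29, adjusted p = 0.0408, and 0.288 with an estimated correlation). Those members were Eomes, from 1.37 to 4.25 FPKM, and Hand1, from 0.577 to 1.79, which are also on the trophectoderm list. Of the p53 target list 8 of 19 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.18, adjusted p = 0.0408, and 0.467 with an estimated correlation), with Gadd45a from 19.8 to 30.5 FPKM, Phlda3 from 17.8 to 25.4 and Btg2 from 6.54 to 9.20, and Zmat3 lower, from 13.8 to 10.8. The calls of these last 3 lists were lost with median centring of the libraries (adjusted p = 0.0668 for trophectoderm, 0.0635 for mesoderm and 0.0585 for p53 targets) and without control replicate 3 (0.0667, 0.0667 and 0.0540). The mesoderm call was also lost without control replicate 1 (0.0569), and the trophectoderm and p53 calls without null replicate 2 (0.0886 each). With a minimum of 5 FPKM trophectoderm (0.191) and p53 targets (0.0556) were lost, without a minimum mesoderm (0.0789), and without chromosomes 11 and Y mesoderm (0.153) and p53 targets (0.0719). The p53 call was also lost with quantile normalization (0.0683) and by fry (0.0586).

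The endoderm list was lower, with 6 of 9 members down and 0 up, or 7 and 0 adjusted over the list alone (median -0.74, adjusted p = 8.75e-04, and 0.307 with an estimated correlation). The members that fell encode extracellular matrix proteins and an endocytic receptor: Lama1 as above, Lamb1 from 21.3 to 10.8 FPKM, Col4a1 from 21.7 to 12.4, Col4a2 from 10.4 to 5.06, Lamc1 and Cubn. The endoderm transcription factor Gata4 did not pass the threshold. The stress and immediate-early list had 7 of 14 members lower and 0 higher, or 8 and 0 adjusted over the list alone (median -0.48, adjusted p = 8.75e-04, and 0.288 with an estimated correlation). The 7 were stress genes, and the tested immediate-early members did not pass the threshold over all genes. The heat-shock genes Hsph1 and Hspa1b fell from 50.2 to 33.1 and from 3.62 to 2.07 FPKM, and Chac1, a glutathione-degrading enzyme induced by cell stress, and Asns, asparagine synthetase, fell from 18.3 to 11.4 and from 233 to 153. The null libraries differed among themselves here, Asns being at 193, 143 and 123 FPKM.

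The other 13 lists did not pass the threshold as sets by camera in the main setting. By fry, 5 of them did: formative and primed epiblast (0.0275), neuroectoderm (0.00946), germline (0.0398), glutathione (0.0120) and signalling targets (0.0201). In the naive pluripotency list 5 of 29 members rose and 12 fell, or 6 and 13 adjusted over the list alone (median -0.07, adjusted p = 0.211): Tbx3 rose from 14.9 to 26.9 FPKM, while Nr0b1 fell from 71.1 to 39.9, Dppa3 from 29.7 to 15.8 and Prdm14 from 10.7 to 5.94. In the formative and primed epiblast list 5 of 12 rose and 2 fell, the same counts as adjusted over the list alone (median 0.14, adjusted p = 0.275), with Sall2 from 2.79 to 5.65 and the DNA methyltransferase Dnmt3a from 15.4 to 24.4 higher and Sox11 from 4.79 to 2.06 and Lef1 from 4.13 to 2.0 lower. In the list of signalling feedback targets 7 of 18 rose and 5 fell, or 9 and 5 adjusted over the list alone (median 0.16, adjusted p = 0.146); Lefty1 and Lefty2, inhibitors of Nodal, fell from 57.0 to 32.2 and from 56.1 to 27.9, and the WNT inhibitor gene Notum from 37.3 to 19.7, while Nodal rose from 34.8 to 44.2 (adjusted p = 0.00163), the WNT target Axin2 from 2.40 to 4.06 (0.00269) and Id1 from 29.6 to 49.6 (0.00388). Imprinted genes were mixed, with 2 of 25 higher and 4 lower, or 2 and 5 adjusted over the list alone (median -0.15, adjusted p = 0.211); Mest rose from 18.7 ± 1.22 to 46.7 ± 17.2 and the Meg3 locus fell from 50.7 to 38.1. Leaving out null replicate 2 made the imprinted list pass, at an adjusted p of 0.00319.

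Of the germline list 4 of 13 rose and 1 fell, or 5 and 1 adjusted over the list alone (adjusted p = 0.146); Hormad1 rose from 13.4 to 21.7 FPKM, while Tex14 fell from 9.42 to 4.76. In the glutathione list 2 of 25 rose and 7 fell, or 3 and 8 adjusted over the list alone (adjusted p = 0.0941, but 0.0442 without the FPKM minimum and 0.0120 by fry, which asks only whether a list moves one way), with the peroxidase gene Gpx1 up from 171 to 306, Gsta3 up from 2.90 to 6.58 and Gpx2 down from 2.94 to 0.996. DNA repair genes moved both ways, 7 of 24 higher and 3 lower, or 8 and 5 adjusted over the list alone (adjusted p = 0.565); the median of -0.01 and the mean of 0.03 differ in sign, and camera gave the upward direction. The mismatch repair gene Msh6 rose from 335 to 410, the checkpoint kinase gene Chek2 from 24.8 to 36.8, and Atr fell from 24.2 to 20.8. Of the hypoxia and glycolysis list 6 of 20 rose and 5 fell, or 8 and 5 adjusted over the list alone (adjusted p = 0.638); Ldha rose from 494 to 664 while Vegfa fell from 10.1 to 6.55, and the median of -0.01 and mean of -0.05 lie opposite to the upward direction given by camera.

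In the neuroectoderm list 0 of 6 rose and 3 fell, as many as adjusted over the list alone (adjusted p = 0.0941), among them Pax6 from 9.96 to 7.85 FPKM and Tubb3 from 67.1 to 51.4. In the fibroblast list, kept as a marker of feeder cells, 1 of 8 rose and 2 fell, as many as adjusted over the list alone (adjusted p = 0.356), with Thy1 up from 1.65 to 2.98, Acta2 down from 3.93 to 1.73 and Tagln down from 8.80 to 4.86 (adjusted p = 0.0444). Of the collagen genes of this list, Col1a1 fell from 0.738 ± 0.132 to 0.0861 ± 0.0281 FPKM. Col1a2 fell from 1.13 ± 0.198 to 0.0776 ± 0.0311. Their means lay under the minimum of 1 FPKM, so they are outside the main test. Without that minimum their limma adjusted p-values were 0.00267 and 0.00149. The fall was not shared by the other collagen genes of the list. Col3a1, also outside the main test, was at 0.363 FPKM in control and 0.395 in null libraries. Col5a2 and Col5a1 did not pass, with log2 fold changes of 0.14 and -0.23 (limma adjusted p = 0.307 and 0.188). Col1a1 and Col1a2 fell along with matrix genes of the endoderm list such as Lama1, Lamb1, Col4a1 and Col4a2. Sparc, another matrix gene of that list, did not fall, at 71.7 FPKM in control and 78.2 in null libraries (limma adjusted p = 0.235). In the interferon list 1 of 7 rose and 1 fell, as many as adjusted over the list alone (adjusted p = 0.723): Bst2 rose from 26.2 to 32.6 and B2m fell from 17.3 to 9.62. Of 10 RNA exosome subunits, Exosc5 rose from 89.3 to 114 and Exosc2 from 65.8 to 79.1, and 0 fell, the same counts as adjusted over the list alone (adjusted p = 0.536). Of the 16 tested genes of the SCAN-domain list, limma called 0 in either direction, over all genes and adjusted over the list alone, and 1 had an unadjusted p under 0.05 (list adjusted p = 0.638). In that list Zkscan5 and Zscan26 were at 13.4 and 15.1 FPKM in control and at 15.1 and 15.5 in null libraries. The list leaves out the Zscan4 genes, which also carry a SCAN domain, stand in the 2-cell-like list and rose: Zscan4c from 11.5 to 24.8 FPKM (adjusted p = 0.000140), Zscan4f from 7.29 to 16.5 (0.00370) and Zscan4d from 9.99 to 17.9 (0.00509). They too are near-identical copies that can share reads.

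**Figure D3:**
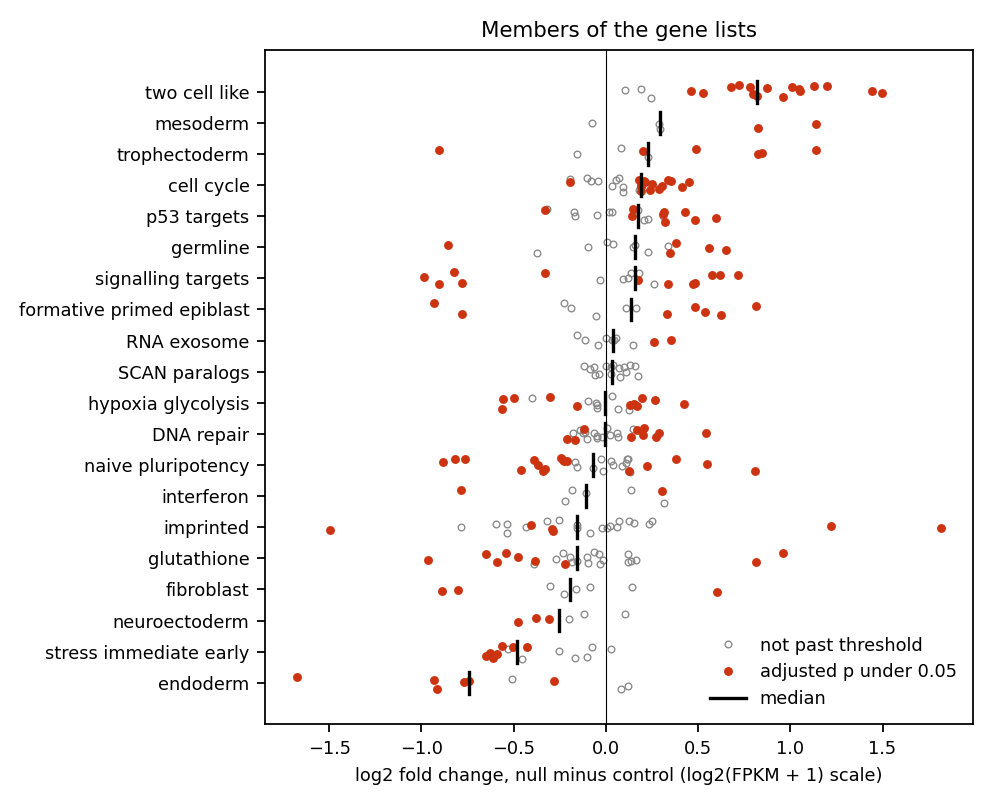
Log2 fold change (null minus control, log2(FPKM + 1) scale) of each tested member of the 20 gene lists, ordered by median, with filled points for members past an adjusted p of 0.05 and a bar at the list median. The 2-cell-like list has its median at 0.82 and the endoderm list at -0.74.

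Genes of chromosome 11 were lower in the null libraries as a group. Of 940 tested, 260 fell and 57 rose, with a median log2 fold change of -0.12 (camera adjusted p = 2.75e-06 with the preset correlation and 0.0181 with an estimated correlation), while the medians of the other autosomes lay between -0.02 and 0.03. The shift ran along the chromosome: 13 of 13 windows of 10 Mb had a median below 0, from -0.23 to -0.05. The median deviations of the libraries were 0.065, 0.064 and 0.054 in control and -0.055, -0.056 and -0.055 in null libraries. Expression alone does not tell which group carried the unusual level. On chromosome Y, 4 of 5 tested genes rose and 0 fell (median 0.53, adjusted p = 0.00993, and 0.601 with an estimated correlation), with median deviations of -0.32, -0.18 and -0.32 in control and 0.21, 0.11 and 0.39 in null libraries: Ddx3y rose from 13.1 ± 0.717 to 26.9 ± 6.28 FPKM, Uty from 14.1 to 20.7, Zfy1 from 0.895 to 2.17 and Uba1y from 5.03 to 7.13, while Eif2s3y was at 76.1 and 84.0 (adjusted p = 0.142).

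**Figure D4:**
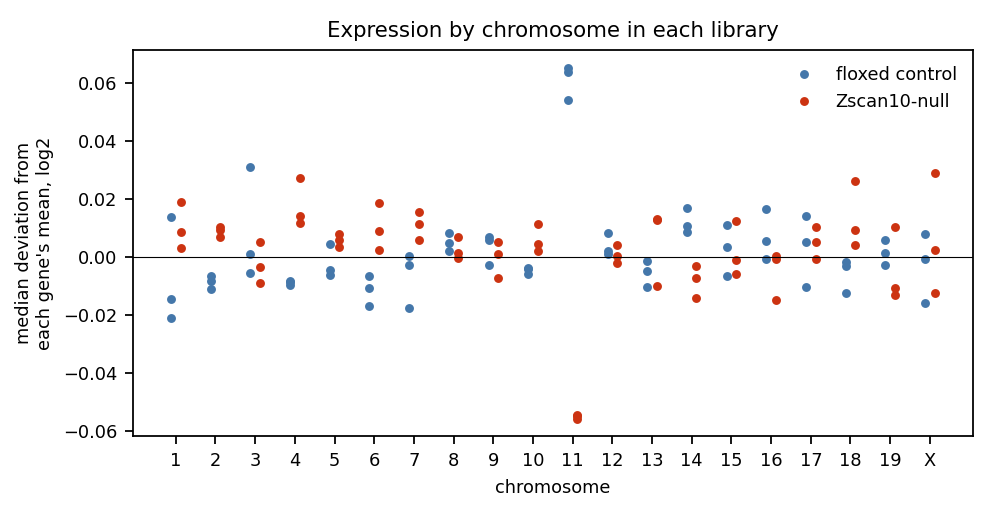
Median deviation, in log2 units, of each library from each gene's mean over the 6 libraries, for the genes of chromosomes 1 to 19 and X. On chromosome 11 the 3 control libraries lie at 0.054 to 0.065 and the 3 null libraries at -0.056 to -0.055.

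Within 500 kb of Zscan10, 17 genes were tested and 1 passed the threshold, Kctd5, which rose from 22.6 ± 1.10 to 25.8 ± 0.213 FPKM (log2 fold change 0.19, SE 0.05, adjusted p = 0.0287). Over all tested loci 25.2% passed, so calls were not more frequent near Zscan10 than elsewhere. The median log2 fold change of the 17 genes was -0.07. The Kctd5 call was lost without control replicate 1 (adjusted p = 0.0911) or 3 (0.0714) and without null replicate 2 (0.0751) or 3 (0.0695), and the count of genes past the threshold ran from 0 to 3 with each library left out.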

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

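Zscan10 stayed lower and past the threshold in every alternative run (log2 fold change -2.89 to -2.76 with each library left out), and no changed locus took the other sign in any setting. The alternatives without short RNA loci and without genes of chromosomes 11 and Y were chosen after seeing the data. The count of changed loci was 2883 and 2910 with pseudocounts 0.1 and 0.01, 2560 without a filter, 2296 with a minimum of 5 FPKM, 2698 after quantile normalization, 2932 after median centring, 3026 with robust eBayes, 3079 without short RNA loci and 2521 without chromosomes 11 and Y. With each library left out it ran from 1697 to 2903. The share of called loci that were higher in null libraries was 50.7% in the main setting, 49.3% after quantile normalization and 58.6% after median centring. The even balance of higher and lower calls thus depends on the scaling. The 2-fold count was 230 and 247 with pseudocounts 0.1 and 0.01, which shrink low genes less, and 59 with the 5 FPKM minimum, which tests fewer genes; it ran from 88 to 123 with each library left out. The replicate numbers did not pair the samples (correlations of same-numbered deviations -0.00242, 0.108 and 0.0527), and the replicate block left 2264 changed loci, 2155 of them shared, and 0 genes near Zscan10; it brought the glutathione list to 0.04999, just under the threshold.

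Lists past the threshold numbered 4 with the 5 FPKM minimum, 4 with median centring, 0 with camera's estimated correlation and 11 with fry, and 4 to 7 with each library left out. Camera's direction turned for SCAN-domain paralogs without a filter (median 0.014) and for hypoxia and glycolysis with quantile normalization (0.025) and without null replicate 1 (-0.086, the lowest of a range up to 0.060 with each library left out). Chromosomes past it numbered 1 with the 5 FPKM minimum, 1 with the estimated correlation, 0 without chromosomes 11 and Y, and 2 to 2 with each library left out. Genes near Zscan10 numbered 2 with pseudocount 0.01, without a filter, with quantile normalization, with robust eBayes and without short RNA loci, 4 at 1 Mb, and 0 to 3 with each library left out. Of the 93 named genes, 87 passed in the main setting and 70 to 84 with each library left out. Except where stated, the cause was not tested. Depth limits loci of low FPKM.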

Other observations

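The tests below of the copy number of chromosome 11 across expression levels and of the amino-acid response were set before their results were seen, and the other tests, including the splits, only after. The gene lists of this part were written after the main results had been seen. Some DNA methylation genes differed in the null libraries: Dnmt3l, Dnmt3a and Dnmt3b, which set or assist new methylation, rose from 196 to 305, 15.4 to 24.4 and 79.4 to 116 FPKM, and the maintenance genes Uhrf1 and Hells from 143 to 185 and from 224 to 286. Tet2, which oxidises methylated cytosine, fell from 37.4 to 31.7. Of 18 such genes 5 rose, 1 fell and 12 did not pass, among them Dnmt1 (adjusted p = 0.0975) and Tet1 (0.876), the same counts as adjusted over the list alone, with a median log2 fold change of 0.10; many had been looked at before the list was written, so its camera p (0.00278 with a preset correlation; adjusted p = 0.0636 with an estimated correlation) is not independent evidence.

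Genes of oocytes and early embryos outside the fixed lists also rose, among them Khdc3 from 28.5 to 64.2, Zp3 from 4.52 to 9.03 and Nlrp9b from 2.48 to 6.83 FPKM, while Ooep fell from 38.1 to 33.6 and Zbed3 from 7.34 to 4.52. Whether the 2-cell-like rise may be part of a wider rise of oocyte-type genes was tried on 10 such genes outside the named ones, of which 7 rose and 2 fell (median 1.11). Most of these had been picked from genes already seen to be higher, so the test is void and leaves the question open. Within Sfmbt2 (mm10 chromosome 2, 10370440 to 10595253) 3 of 8 tested short RNA loci rose with the host gene: Mir669k from 243 to 1329, Mir669j from 273 to 921 and Mir669i from 81.4 to 585 FPKM. Mir18b was at 3312, 3040 and 3325 FPKM in control and listed at 0 in each null library; Snord35b and Snord8 were listed at 0 in each control library and were at 1538, 1387 and 1518 and at 252, 455 and 249 FPKM in null libraries.

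A hypothesis drawn from the stress list is a lower amino-acid response in the null cells. Asns, Chac1 and Atf4 (169 to 120 FPKM) had fallen, so 28 other targets of that response were tested, with the bound set at a median below -0.1: 22 fell and 0 rose, or 24 and 1 adjusted over the list alone, with a median of -0.42. The 1 that rose was Ddit4, with a log2 fold change of 0.24 (limma adjusted p over all genes 0.0782). Psat1 and Phgdh, of serine synthesis, fell from 229 to 125 and from 81.0 to 57.3 FPKM, and the transcription factor gene Atf5 from 20.8 to 12.1. Camera gave p = 6.88e-10 with a preset correlation and an adjusted p of 0.185 with an estimated correlation, and the median deviations of the null libraries were 0.01, -0.27 and -0.37 against 0.22, 0.21 and 0.20 in control, so null replicate 1 differed from the other null libraries. A difference in medium or feeding between cultures would give the same pattern, and no such difference was tested.

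Esr1 was almost absent from the null libraries, at 0.486% of control. Loss or silencing of a wide region around it does not account for this: the 5 tested genes within 1 Mb of its start had a median log2 fold change of -0.019 and ran from -0.29 to 0.58, against -3.58 for Esr1. These 5 all lie on one side, and 3 of them passed the threshold. On the other side, looked at later, Fbxo5 rose from 89.2 to 112 FPKM (log2 fold change 0.32, adjusted p = 0.00164) and Mtrf1l was at 2.78 and 2.19 (-0.25, adjusted p = 0.123), while the 2 loci of the nearest gene, Syne1, were under 1 FPKM in both groups, at 0.419 and 0.448 and at 0.465 and 0.322. A loss limited to Esr1 itself remains open. A candidate explanation is a Cre fusion with a part of the estrogen receptor in the inducible line, counted as Esr1 in control cells. This explanation requires that the null subclone lacked the fusion or did not express it, which was not tested. Such a fusion cannot be told apart from expression of the gene itself, since the files give 0.486% as 1 value for the whole locus and no value per exon. A difference of the subclone, or an effect of losing Zscan10, also remains open and was not tested.

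Zscan10 fragments remained in the null libraries at 12.8, 10.3 and 12.7% of control, a mean of 11.9%. Undeleted control cells mixed into the null cultures would bring Esr1 at the same share, but Esr1 was at 0.253, 0.457 and 0.749% of control, so the highest Esr1 share, 0.749%, lies below the lowest Zscan10 share. This comparison covers only undeleted cells that express Esr1 as the control libraries do. Undeleted cells that almost lack Esr1, like the null cells, remain open. Fragments from exons outside the deletion could give the remaining 11.9%, which cannot be told apart here because no exon-level value was analysed.

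Chromosome 11 was lower as a whole in the null libraries. Composition does not account for it: after a smooth fit on GC content, transcript length and expression the residual median was -0.12 (95% interval -0.14 to -0.11). A few strongly regulated genes do not either, since 13 of 13 windows lay below 0, and 71.1% of its genes did against 48.9% elsewhere. A different number of chromosome 11 copies in part of the cells would shift genes of every expression level, and the medians of the log2 ratio without a pseudocount were -0.19, -0.16 and -0.072 in the genes of low, middle and high FPKM, equal shares of the chromosome, with 95% intervals of -0.26 to -0.16, -0.19 to -0.13 and -0.10 to -0.055. Each median lay beyond the bound of -0.06 set before, but the last interval reaches past it, and a change of copies alone would shift the 3 alike, which they were not: an extra copy in control cells would be put in 29.6, 24.5 and 11.05% of the cells by the 3 values. So the values do not settle it. Loss in null cells and change over the whole chromosome without a copy change also remain open, and no DNA was measured.

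For chromosome Y, loss of the chromosome from part of the control cells would shift its genes alike, but the log2 fold changes of Ddx3y and Eif2s3y differed by 0.82 (SE 0.16), which argues against it as the whole cause, unless reads shared with their X copies hide part of the change. These genes had the highest (0.96) and lowest (0.14) log2 fold change of the 5 tested and were paired after their values were seen. The SE also treats them as independent, so the evidence is weaker than it looks.

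The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Every other split mixes the real groups unevenly and so keeps part of the group difference. Its counts therefore do not show what chance alone gives. The real split gave 2894 changed loci, 1 of the 10 splits reaching that, and the highest other split gave 4. For 2-fold changes the real count was 99 and the highest other 4 (1 split as large), for gene lists 7 and 6 (1 split), for chromosomes 2 and 2 (3 splits), and for genes near Zscan10 1 and 0 (1 split).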
